A study of Danio rerio with 6 samples.

How the data were processed

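The samples were 6 libraries from whole zebrafish embryos, 3 of the control group and 3 of the FBSA group, each from 10 pooled embryos, grouped by the treatment given in the labels. Per the labels' protocols, embryos were freed of the chorion at 4 h after fertilization, exposed without renewal from 8 h and harvested at 48 h, and single-end libraries were prepared with the Lexogen QuantSeq 3′ FWD kit. The submitters' processing notes name STAR, HTSeq, DESeq2 and the genome build GRCz11. Versions, annotation, filters and the treatment of reads matching several genes were not given in the sources used here. The libraries carry separate pools of embryos per the labels, but whether the pools came from separate clutches was not given, so p-values measure the spread between these pools.

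The deposited table holds log2 values for 24462 Ensembl genes in 6 value columns, although it is named as normalized counts. Its header holds 6 names and none for the gene column, so each name stands 1 cell to the left of its values, and the names were assigned in that order after shifting them by 1 cell. Read without the shift, the column taken here as control replicate 3 would carry an FBSA name, and the results without that library are therefore given in the closing section. All 6 columns share a floor of 6.52, and the values have the closed form of a variance-stabilising transformation. Undoing it gave whole reads per gene divided by 1 size factor per library: 100.0% of the values above the floor lay within 0.1 of a whole number, the largest distance being 0.0163. The recovered factors equalled those of the median-of-ratios method within 2.21e-08%. The recovery was tested on simulated reads put through the same transformation.

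The design, fixed before the data were examined, had taken the deposited values as counts divided by size factors. The main test was therefore run on the recovered normalized counts, as log2(normalized count + 1), and the deposited log2 values served as an added alternative. Fold changes are on the log2(value + 1) scale and understate the change of low genes. Genes with 10 or more normalized counts in at least 3 libraries were tested with limma 3.58.1 in R 4.3.3 (linear model with the group as the only term, moderated with a trend, two-sided), with Benjamini-Hochberg adjustment over all 16890 genes and a threshold of 0.05. On simulated counts for these 16890 genes with 200 changed, the test called 5.97% of genes changed 1.5-fold, 25.4% of those changed 2-fold and 74.2% of those changed 4-fold, and 5 of its 75 calls were unchanged genes. Recovered totals per library ran from 23906021 to 33356411 reads. Comparison of the recovered reads between the libraries of every pair gave a chi-square per degree of freedom of 10.8 to 57.3, so no library was a copy of another within sampling noise.

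Symbols came from a table of gene names, which matched 22817 of the 24462 identifiers, and 1523 symbols belong to more than 1 identifier. Symbols are printed as in that table, many in capitals. No gene coordinates were used. Before the data were examined, 37 lists (18 for pathways and 19 for cell types) and 22 families by symbol pattern were fixed. Of 1337 list symbols, 907 matched directly, 323 matched after a paralogue suffix was removed, which can add a paralogue, and 107 did not match. Lists with at least 5 tested genes were tested with camera (preset correlation 0.01, and again with an estimated correlation) and with fry, adjusted over the 59 lists. The limma p-values of members were also adjusted over each list alone. Those counts were not named in the fixed design and carry no adjustment across the 59 lists. Genes with related symbols, such as he1.1 and he1.2 or genes sharing the symbols SLC16A9, ACTA1, ARRDC3 and DLL1, may have reads that match both. This was not checked, and their separate values are uncertain.

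Named genes followed a rule fixed in advance. It took the 10 largest and 10 smallest log2 fold changes among genes past the threshold with a mean of 20 or more normalized counts, all FBSA libraries on the same side of all controls and a symbol that is not a placeholder. It also took up to 4 members past the threshold of each list called by camera and up to 2 of each other list, and cyp1a (CYP1A1 in the table), cyp3a65, hsp70l and pck1 in all cases. A further gene, gstp1, was not matched. Alternatives covered the pseudocount, the filter, the scaling, the replicate number as a block, robust moderation, limma-voom, each library left out, thinned reads and stricter thresholds. Intervals were not computed for shares of reads, and reads without molecular identifiers are not independent molecules. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 was used for the recovery and figures.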

Results

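Gene expression was measured by 3′ RNA sequencing in whole embryos of Tropical 5D, a wild-type zebrafish line. Embryos were held from 8 h after fertilization either in 47 µM perfluorobutane sulfonamide (FBSA), a short-chain perfluorinated sulfonamide, or in the solvent control. Both groups had 0.5% methanol, and embryos were harvested at 48 h. Each group had 3 libraries, and each library came from a pool of 10 embryos. The comparison addressed how the developmental exposure altered transcript levels. The series also set this library type against standard RNA sequencing, which was not analysed here. The control libraries held 32108756, 24348679 and 23906021 reads in genes and the FBSA libraries 33356411, 29475787 and 27719471, with means of 26787819 ± 4613379 and 30183890 ± 2884412 reads (SD, n = 3 each). Between 20293 and 21367 genes had at least 1 read in a library. A gene without a symbol, ENSDARG00000080337, took 21.9% ± 0.636 of the reads in control and 21.5% ± 1.29 with FBSA (SD, n = 3 each).

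Of 16890 genes tested, 96 rose and 23 fell (limma, Benjamini-Hochberg adjusted p under 0.05), and 50 of the higher and 7 of the lower genes changed by 2-fold or more. At an unadjusted p under 0.05 the numbers were closer, with 1240 genes higher and 1055 lower, and the median log2 fold change of all genes tested was −0.0009. The largest increases among named genes were in SLC16A9, of the monocarboxylate transporter family, irg1l, mcoln3a and cbx7a. Among named genes the decreases were led by igfn1.3, gvin1l2, AMPD1 and P4HA1, which encodes a subunit of collagen prolyl 4-hydroxylase. All 119 genes had the 3 FBSA libraries on the same side of the 3 controls. Selection at this threshold favours such genes, so this is no separate support. Of all genes tested, 19.9% were apart in this way, where chance gives 10%. The number of genes past the threshold was 53 without control replicate 3, 57 without FBSA replicate 1 and 58 without FBSA replicate 2. The lower genes alone numbered 4 without control replicate 3, 5 without FBSA replicate 1, 12 without control replicate 1 or FBSA replicate 2, 15 without control replicate 2 and 23 without FBSA replicate 3.

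**Figure D1:**
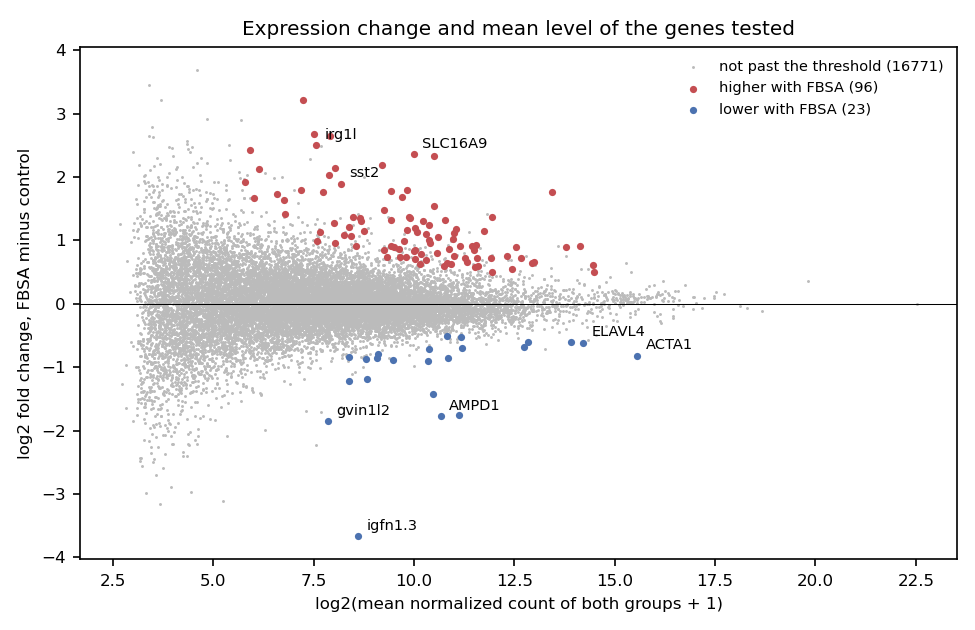
Log2 fold change of FBSA minus control (y axis) against the log2 mean normalized count of both groups plus 1 (x axis), 1 point per gene tested. The 96 genes higher with FBSA are red, the 23 lower genes are blue, and SLC16A9, irg1l, sst2, igfn1.3, AMPD1, gvin1l2, ACTA1 and ELAVL4 are named.

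SLC16A9 is the symbol of 2 gene identifiers, and both rose. ENSDARG00000104687 went from 325 ± 47.8 to 1707 ± 506 normalized counts (SD, n = 3 each), a 5.11-fold increase (log2 fold change 2.35 ± 0.20 SE, limma adjusted p = 0.000755). ENSDARG00000013926 rose 6.28-fold to 418 ± 264 normalized counts (limma adjusted p = 0.0049). SLC16A6, of the same transporter family, rose 3.44-fold, from 308 ± 49.9 to 1077 ± 285 normalized counts (limma adjusted p = 0.00146). The gene irg1l rose 5.67-fold and mcoln3a, of the mucolipin channel family, 5.36-fold, while the hormone genes sst2 (somatostatin) and prl (prolactin) rose 3.72-fold and 3.77-fold and cbx7a, a Polycomb chromobox gene, 4.11-fold. ARRDC3 (ENSDARG00000036028), an arrestin domain gene, rose 3.49-fold and agt, which encodes angiotensinogen, 3.47-fold. Their limma adjusted p-values lay between 0.00315 for sst2 and 0.0307 for cbx7a. Another identifier with the symbol ARRDC3, ENSDARG00000052690, which the rule for named genes did not take, rose 2.36-fold (limma adjusted p = 0.0311). The increase in cbx7a was uneven, with 739 normalized counts in FBSA replicate 2 against 219 and 222 in the other FBSA libraries.

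Skeletal muscle genes were among those that fell. In the other direction, MYOD1, a muscle determination gene chosen after its values were seen, rose (log2 fold change 0.73, limma adjusted p = 0.0383). The largest decrease was in igfn1.3, from 701 ± 90.1 to 76.7 ± 64.3 normalized counts (SD, n = 3 each), 12.6-fold lower (log2 fold change −3.66 ± 0.57 SE, limma adjusted p = 0.0105). FBSA replicate 2 held 15.0 normalized counts of igfn1.3 against 71.9 and 143 in the other FBSA libraries, and without it the log2 fold change was −2.77 (limma adjusted p = 0.00139). AMPD1, the muscle AMP deaminase gene, fell 3.42-fold from 2469 ± 392 to 786 ± 362 normalized counts (limma adjusted p = 0.0178). LDHA, a lactate dehydrogenase gene, was 1.81-fold lower and GYS1, a glycogen synthase gene, 1.80-fold lower (limma adjusted p = 0.0225 and 0.0348). Of 49 fast skeletal muscle genes tested, 3 fell, 0 rose and 46 did not pass, and adjusted over the list alone 4 fell and 1 rose. The 3 were both identifiers of the skeletal actin gene ACTA1, with log2 fold changes of −0.82 (ENSDARG00000055618) and −0.68 (ENSDARG00000036371), and the fast troponin I gene TNNI2 (ENSDARG00000029995), with −0.90. The calls of AMPD1, LDHA, GYS1, TNNI2 and both ACTA1 identifiers were each lost without at least 1 library, and those of igfn1.3 and AMPD1 with robust moderation (limma adjusted p = 0.208 and 0.22). As a list these genes were lower (camera adjusted p = 0.000378; adjusted p = 0.317 with an estimated correlation). None of the 17 slow skeletal muscle genes passed. Of 39 hypoxia and glycolysis genes, LDHA fell and 38 did not pass, with 3 rising and 3 falling when adjusted over the list alone, and that list was not past the threshold (camera adjusted p = 0.309). Other decreases were in gvin1l2, which fell 3.61-fold, in P4HA1 (2.28-fold), DAO (D-amino acid oxidase; 1.85-fold), the bicarbonate transporter gene slc4a10a (1.84-fold) and NECAB2 (1.78-fold).

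**Figure D2:**
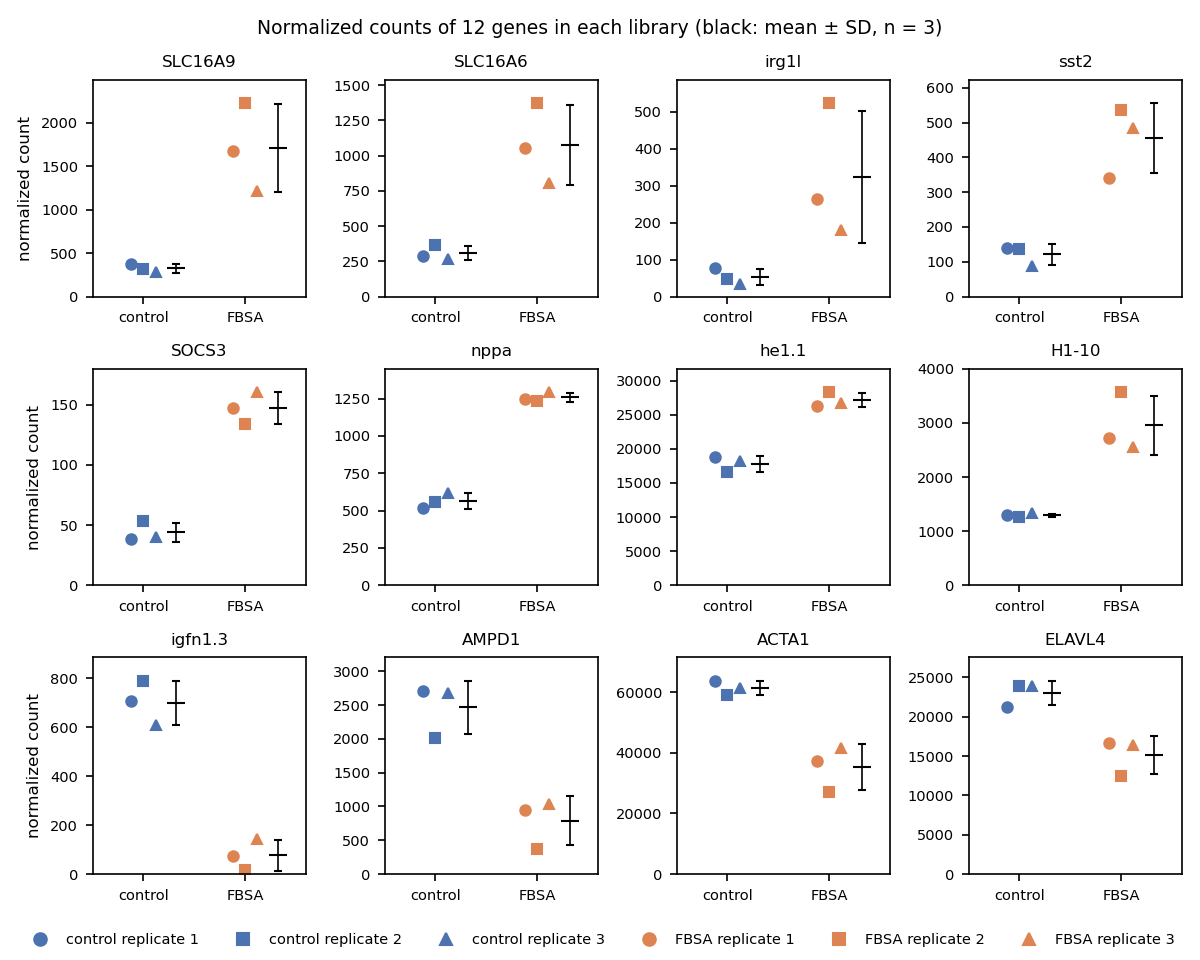
Normalized counts (y axes, linear from 0) of 12 genes in the 3 control (blue) and 3 FBSA (orange) libraries, with the mean ± SD of each group in black. SLC16A9 is ENSDARG00000104687 and ACTA1 is ENSDARG00000055618, and in every panel the 3 FBSA libraries lie apart from the 3 controls.

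Gene lists for pathways, gene families and cell types, 59 in all, were tested with camera. With a preset correlation of 0.01 between genes, 18 lists were higher and 13 lower with FBSA. With an estimated correlation 0 lists passed, the smallest adjusted p being 0.291, and 8 had an unadjusted p under 0.05. The directional test fry, which asks whether a list's genes move on balance in one direction, also called 0 lists, with 18 at an unadjusted p under 0.05, and its test for change in either direction called 24. Control replicate 2 and FBSA replicate 2 lay at opposite ends of the leading principal component, which held 34.3% of the variance, at −65.5 and 54.0, and in 15 of the 31 lists these were the lowest and the highest library, in either order. Without FBSA replicate 2, 10 of the 31 calls were lost, and the lower lists numbered 8. The calls lost without at least 1 library were those of ionotropic receptors, complex I, kidney, collagens, mitochondrially encoded genes, xenobiotic metabolism, mitochondrial ribosomal proteins, aryl hydrocarbon receptor targets, the unfolded protein and integrated stress responses, red blood cells and fatty acid synthesis, 11 in all. The list means of the 3 FBSA libraries lay apart from those of the 3 controls in 20 of the 31 lists. They overlapped in 11: immediate early genes, glutathione transferases, interferon response, complex I, kidney, xenobiotic metabolism, mitochondrial ribosomal proteins, receptor targets, the unfolded protein and integrated stress responses, red blood cells and fatty acid synthesis.

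Inflammatory and acute phase genes gave the largest list increase by mean among the lists past the threshold. Of 24 tested, 5 rose, 0 fell and 19 did not pass, and 15 rose when adjusted over the list alone. Of the 34 symbols fixed for this list 5 were not matched, so members past the threshold may be missing from these counts. The list fixed acod1, and irg1l, which rose 5.67-fold, was not counted in it. Whether irg1l is the gene meant by that symbol was not checked. SOCS3, an inhibitor of cytokine signalling, rose 3.33-fold from 43.9 ± 8.23 to 147 ± 13.2 normalized counts (SD, n = 3 each; limma adjusted p = 0.0105). The transcription factor genes CEBPD and CEBPB rose 2.78-fold and 2.19-fold, and the complement gene c3a.1 rose 1.66-fold. Each of these 4 calls was lost without at least 1 library. The fifth, nfkbiaa, an inhibitor of NF-κB chosen after its values were seen, had a log2 fold change of 1.28 ± 0.23 SE. The list was higher as a whole (camera adjusted p = 2.37e-13; adjusted p = 0.291 with an estimated correlation), with a mean log2 difference from control of −0.25 in control replicate 2 and 1.32 in FBSA replicate 2. Of 27 immediate early genes, BTG2 (1.65-fold) and CEBPB rose and 25 did not pass, while 6 rose when adjusted over the list alone (camera adjusted p = 5.19e-05; adjusted p = 0.291 with an estimated correlation). None of 11 interferon response genes passed, over all genes or adjusted over the list alone, although the list was higher (camera adjusted p = 0.0023; adjusted p = 0.335 with an estimated correlation), and its means were 0.07, −0.62 and 0.54 in the control libraries and 0.47, 1.51 and 0.57 in the FBSA libraries, so the groups overlapped. That call was lost without both libraries numbered 2 (camera adjusted p = 0.41). Of 13 glucocorticoid targets 0 passed and 4 rose when adjusted over the list alone (camera adjusted p = 0.00213; adjusted p = 0.291 with an estimated correlation).

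Of 38 ionocyte and epidermis genes, 2 rose and 36 did not pass, while 16 rose and 3 fell when adjusted over the list alone (camera adjusted p = 2.9e-06; adjusted p = 0.291 with an estimated correlation). They were ATP1B1 (ENSDARG00000076833), a sodium pump subunit gene, at 1.94-fold, and the claudin gene cldne at 2.16-fold. Among 30 claudins, genes of tight junctions, cldne and cldn3c (1.54-fold) rose and 28 did not pass, with 8 rising when adjusted over the list alone (camera adjusted p = 4.4e-05; adjusted p = 0.291 with an estimated correlation). The hatching enzyme genes he1.1 and he1.2 rose 1.52-fold and 1.85-fold, the former from 17824 ± 1161 to 27133 ± 1057 normalized counts (SD, n = 3 each). They were 2 of 11 hatching gland genes, of which 5 rose when adjusted over the list alone (camera adjusted p = 0.00067; adjusted p = 0.291 with an estimated correlation). Of 23 heart muscle genes, the natriuretic peptide genes nppa (2.24-fold; limma adjusted p = 0.00146) and nppal (2.67-fold; lost without a filter, with limma adjusted p = 0.0581) rose and 21 did not pass, and 3 rose when adjusted over the list alone (camera adjusted p = 0.00115; adjusted p = 0.291 with an estimated correlation). The phosphate transporter gene SLC20A1 rose 2.04-fold as the only one of 23 kidney genes to pass, over all genes or adjusted over the list alone (camera adjusted p = 0.0194; adjusted p = 0.317 with an estimated correlation).

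Of 90 neuron and synapse genes, ELAVL4, which encodes a neuronal RNA-binding protein, fell from 23039 ± 1565 to 15168 ± 2388 normalized counts (SD, n = 3 each; 1.53-fold; limma adjusted p = 0.0353) and 89 did not pass, with 2 falling when adjusted over the list alone. The list was lower (camera adjusted p = 2.75e-08; adjusted p = 0.317 with an estimated correlation). Of 50 neural progenitor and glia genes, the proneural gene ascl1a rose 1.98-fold and 49 did not pass, while 22 rose and 2 fell when adjusted over the list alone (camera adjusted p = 2.76e-08; adjusted p = 0.291 with an estimated correlation). Of the 53 symbols fixed for that list 5 were not matched, so members past the threshold may be missing from these counts. Both identifiers of the symbol DLL1, of a Notch ligand, rose past the threshold but were not counted in this list. The list fixed the delta genes dla, dlb and dld, and whether these identifiers are among them was not checked. None of 55 cell cycle and DNA replication genes passed, 5 rose when adjusted over the list alone, and 54 had a positive log2 fold change with a median of 0.32 (camera adjusted p = 8.24e-14; adjusted p = 0.291 with an estimated correlation). Of 25 p53 and DNA damage genes BTG2 rose and 24 did not pass, with 8 rising when adjusted over the list alone (camera adjusted p = 3.03e-05; adjusted p = 0.313 with an estimated correlation). Voltage-gated channels (37 genes) and ionotropic receptors (36 genes) were lower as lists with 0 members past the threshold over all genes or adjusted over the list alone (camera adjusted p = 0.000122 and 0.00726; adjusted p = 0.317 with an estimated correlation for each). Their means in FBSA replicate 2 were −0.79 and −0.69, against −0.14 and −0.15 in FBSA replicate 3. Both list calls were lost without both libraries numbered 2 (camera adjusted p = 0.075 and 0.0638).

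**Figure D3:**
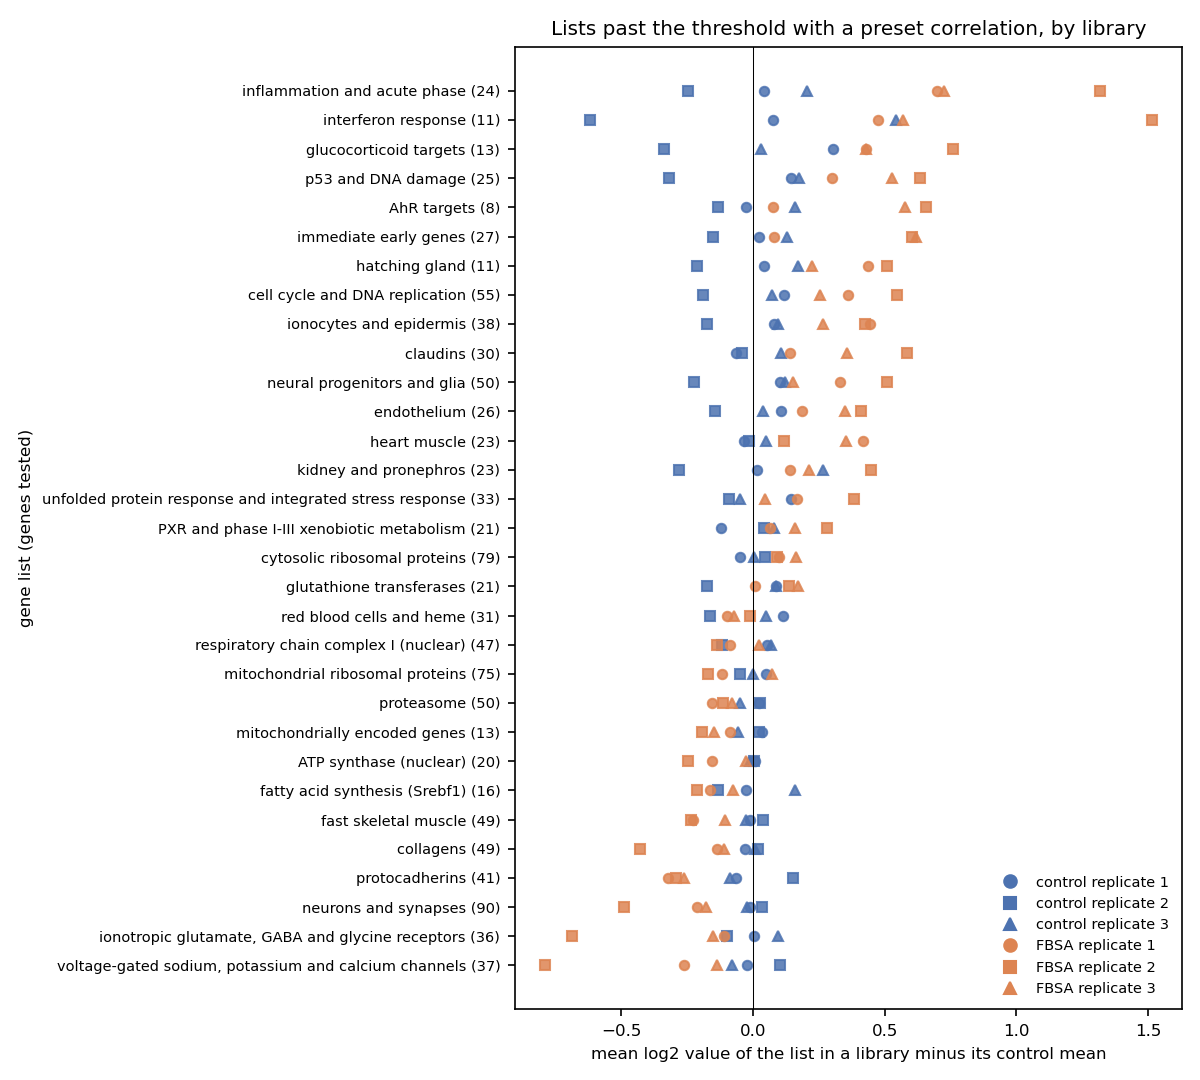
Mean log2 value of each list in a library minus the control mean (x axis) for the 31 lists past the threshold with a preset correlation (y axis, number of genes tested in parentheses), with control libraries in blue and FBSA libraries in orange. FBSA replicate 2 reached 1.32 for inflammation and acute phase and −0.79 for voltage-gated channels.

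CYP1A1, the usual marker of the aryl hydrocarbon receptor, had 35.5 ± 15.5 normalized counts in control and 58.7 ± 26.9 with FBSA (SD, n = 3 each, limma adjusted p = 0.565). None of the 8 receptor targets passed, but all 8 had a positive log2 fold change, with a median of 0.38. As a list the receptor targets were higher (camera adjusted p = 0.0334, and adjusted p = 0.317 with an estimated correlation). The call of that list was lost with either other filter (camera adjusted p = 0.0724 and 0.0626). The drug-metabolizing gene cyp3a65 had 6.94 ± 1.98 and 21.4 ± 7.88 normalized counts (limma adjusted p = 0.32). The heat shock gene hsp70l had a log2 fold change of −0.07 ± 0.53 SE and PCK1, a gluconeogenesis gene, 0.77 ± 0.57 SE, and neither passed. MGST1, a microsomal glutathione transferase gene, rose 1.55-fold, the only one of 21 glutathione transferases past the threshold, over all genes or adjusted over the list alone (camera adjusted p = 0.00183; adjusted p = 0.291 with an estimated correlation). Of 33 genes of the unfolded protein and integrated stress responses, CHAC1 (1.65-fold), CEBPB and the serine synthesis gene PHGDH (1.56-fold) rose and 30 did not pass, with 9 rising and 2 falling when adjusted over the list alone (camera adjusted p = 0.0334; adjusted p = 0.317 with an estimated correlation), and the call of the list was lost without a filter (camera adjusted p = 0.0776). None of 24 oxidative stress genes passed and their list did not either (camera adjusted p = 0.0627).

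The 79 cytosolic ribosomal protein genes were higher as a list by a median log2 fold change of 0.10 (camera adjusted p = 3.03e-05; adjusted p = 0.423 with an estimated correlation). Proteasome genes were lower by a median log2 fold change of −0.16 over 50 genes (camera adjusted p = 4.3e-05; adjusted p = 0.291 with an estimated correlation), and nuclear ATP synthase genes also by −0.16 over 20 genes (camera adjusted p = 0.000809; adjusted p = 0.369 with an estimated correlation). No member of these lists passed over all genes tested, and adjusted over the list alone 1 ATP synthase gene fell. Endothelial and xenobiotic metabolism genes were higher as lists, and protocadherins, collagens, red blood cell, fatty acid synthesis, complex I, mitochondrially encoded and mitochondrial ribosomal protein genes were lower, with 0 members past the threshold over all genes (camera adjusted p from 0.000378 to 0.0472; adjusted p from 0.291 to 0.545 with an estimated correlation). Adjusted over the list alone, 2 collagen genes fell, 5 fatty acid synthesis genes fell and 1 rose. The other 28 lists, among them lens, photoreceptor, pigment cell, notochord and circadian clock genes, were not past the threshold (smallest camera adjusted p = 0.0612). Among these, c9 (1.68-fold) and c3a.1 rose among 40 liver and yolk genes, with 4 rising and 1 falling when adjusted over the list alone. FN1, the fibronectin gene, rose 1.80-fold among 67 cartilage, bone and matrix genes, where P4HA1 fell, with 1 rising and 4 falling when adjusted over the list alone. The linker histone gene H1-10 rose 2.26-fold, from 1295 ± 31.6 to 2954 ± 543 normalized counts (SD, n = 3 each), among 21 histones, of which 4 rose when adjusted over the list alone. The keratin gene krt92 rose 1.82-fold (limma adjusted p = 0.0493, and 0.0517 with a pseudocount of 0.5) among 17 keratins, of which 4 rose and 4 fell when adjusted over the list alone, and sst2 was 1 of 18 intestine and pancreas genes, of which 2 rose when adjusted over the list alone. Of 44 named genes past the threshold, 15 passed again without each library in turn and 29 were lost without at least 1 library. The 15 were both identifiers of SLC16A9, irg1l, sst2, ARRDC3 (ENSDARG00000036028), SLC16A6, igfn1.3, gvin1l2, P4HA1, nppa, SLC20A1, ATP1B1, cldne, he1.1 and H1-10. With robust moderation cbx7a, ARRDC3, he1.2 and krt92, like igfn1.3 and AMPD1, did not pass (limma adjusted p = 0.0992, 0.0976, 0.0567 and 0.0565 for the first 4).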

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

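The deposited log2 values, the equal depth and the joint omission of both libraries numbered 2 were chosen after seeing the data. Planned tests with edgeR and DESeq2 were not run. The recovered reads would allow them, but the rules set in advance keep these tools for values deposited on a linear scale, and limma-voom was run on the recovered reads instead. Against 96 higher and 23 lower genes, pseudocounts, filters, scalings, robust moderation, limma-voom, thinning to 50, 25 and 10 percent of reads (97, 96 and 84 higher), the deposited values (106 and 26), equal depth (99 and 22) and the joint omission (106 and 32) gave counts within 1.5 times. The 119 genes kept their direction in every refit, the thinned draws not being compared. Leaving out libraries could not have reversed it, because all 119 had their FBSA libraries apart from their controls. Stricter thresholds gave 50 and 7 genes at 2-fold or more and 36 and 3 at an adjusted p under 0.01. Without each library in turn, the higher genes ranged from 46 to 87, the lower genes from 4 to 23, the higher lists from 15 to 19 and the lower lists from 8 to 16, where fewer samples reduce power. Without control replicate 3, whose column depends on the header reading, 49 genes were higher and 4 lower, and 50 of the 53 were among the 119. The replicate block gave 40 higher and 7 lower genes, and 19 and 12 lists. For libraries of the same replicate number, deviations from the group means correlated at 0.02, −0.14 and −0.005 across genes. Libraries of unlike number gave values from −0.14 to 0.13, so no shared deviation was seen. What the numbers stand for was not given, and with 3 libraries per group a pairing cannot be excluded. Of the fixed lists, 0 were higher and 0 lower with an estimated correlation, and likewise 0 and 0 with fry. Genes that did not pass changed sign in 3 cases: hsp70l ranged from −0.53 to 0.45 without each library in turn, at 0.45 without control replicate 3 and 0.43 without FBSA replicate 3, and PCK1 was −0.26 without both libraries numbered 2; the cause was not tested. Of 44 named genes past the threshold, 12 passed in every refit: both identifiers of SLC16A9, irg1l, sst2, SLC16A6, gvin1l2, P4HA1, nppa, SLC20A1, ATP1B1, cldne and H1-10. The replicate block lost 24: he1.1 and, among those also lost without a library, mcoln3a, cbx7a, prl, agt, DAO, slc4a10a, LDHA, GYS1, NECAB2, CHAC1, PHGDH, BTG2, SOCS3, CEBPD, nppal, c9, he1.2, ELAVL4, ascl1a, FN1, krt92, cldn3c and MGST1. Total-sum scaling lost cbx7a, PHGDH, nppal, c9, ascl1a, FN1, krt92 and cldn3c, and quantile normalization PHGDH, nppal and krt92. With limma-voom cbx7a, nppal and krt92 were lost, with the deposited values cbx7a, without a filter nppal, and with a pseudocount of 0.5, the filter of 50 or the median-ratio scaling krt92. No list past the threshold changed the sign of its mean. Of the 31 lists, 20 passed again without each library in turn and 11 were lost without at least 1 library. With all libraries and the preset correlation, 4 were lost, and interferon response, with 4 genes left, was not tested with the filter of 50. Aryl hydrocarbon receptor targets were lost with either other filter, the unfolded protein and integrated stress responses without a filter, and collagens with a filter of 50 (camera adjusted p = 0.073). Fatty acid synthesis was lost with total-sum scaling, quantile normalization, the replicate block and limma-voom (camera adjusted p = 0.0538, 0.0506, 0.0504 and 0.053).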

Other observations

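Among the tests below, the split of the libraries for the gene count, the omission of both libraries numbered 2, the equal depth and the crystallin test were chosen after the result was seen. The genes of this paragraph and the next were also chosen after their values were seen. Genes past the threshold included the neutral amino acid transporter genes SLC1A4 (log2 fold change 1.11 ± 0.14 SE) and SLC43A2 (0.64 ± 0.12 SE), and the aminoacyl-tRNA synthetase genes AARS1 (0.59 ± 0.11 SE), NARS1 (0.59 ± 0.11 SE) and EPRS1 (0.49 ± 0.10 SE), with limma adjusted p-values from 0.00306 for SLC1A4 to 0.0484 for EPRS1. ODC1, the ornithine decarboxylase gene, rose from 2112 ± 267 to 4762 ± 1192 normalized counts, while oaz1b, an antizyme gene, fell from 18486 ± 202 to 12279 ± 1725 (SD, n = 3 each).

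Both identifiers that share the symbol DLL1, of a Notch ligand, rose, with log2 fold changes of 0.69 (ENSDARG00000020219) and 0.66 (ENSDARG00000010791). The telomerase gene TERT rose from 176 ± 14.3 to 344 ± 6.25 normalized counts, MYOD1, a muscle determination gene, from 483 ± 64.4 to 797 ± 28.7, and the cathepsin L genes ctsla and ctslb.4 by log2 fold changes of 0.91 and 0.90. The topoisomerase gene TOP1 fell from 8920 ± 234 to 5869 ± 613 normalized counts (SD, n = 3 each).

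Of the 119 genes past the threshold 80.7% were higher, whereas at an unadjusted p under 0.05 the wider set held 1240 higher and 1055 lower genes. Of the 10 splits of the 6 libraries into 3 and 3, only 1, the real one, gave as many genes, and the highest of the others gave 4. With 10 splits a share under 0.05 cannot be reached. Scaling of the libraries and the deeper FBSA libraries were weighed as causes of the imbalance. The share was 74.4% or more under the total-sum, median-ratio and quantile scalings and 81.8% with all libraries thinned to the same depth. These values argue against the depth gap and the choice among these scalings as the whole cause. However, the total-sum and median-ratio factors lay only between 0.963 and 1.03, so a larger error of scaling was not tested. What causes the imbalance among the 119 stays open.

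The list calls came with control replicate 2 and FBSA replicate 2 far apart. Without both libraries 20 of the 31 lists were called in the same direction, so those 20 calls did not need these libraries. Splits that mix the groups called up to 24 lists with the same test, so this number cannot decide where the calls come from. A difference between embryo pools that exists without exposure was also weighed: across 16890 genes, which are not independent replicates, the difference of control replicate 2 from control replicate 1 correlated at −0.083 with FBSA minus control replicate 3, and at 0.01 with the other controls exchanged. By the bound of −0.1, set before the test, the value alone lay on the side against this cause. However, control replicate 1 minus control replicate 3 correlated at 0.095 with FBSA minus control replicate 2. Values of this size thus arise in either direction, and the bound cannot decide. A margin, the gap between the first 2 correlations, was added after the value was seen, and with it the value is too close to the bound to decide. The real split, 1 of the 10, called the most lists, but splits that mix the groups, each still parting them 2 to 1, called between 4 and 24 lists with at most 4 genes, and the 10 splits are too few for a share under 0.05. Younger embryos with FBSA could give higher progenitor and cell cycle genes and lower neuron and muscle genes, but crystallin genes, which rise as the lens forms, differed by −0.0028 on the log2 scale with means from −0.20 to 0.15 over the FBSA libraries, and this cannot be told apart without a stage series.

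The hypothesis that cytosolic aminoacyl-tRNA synthetase genes rise as a group was tested on the 16 other than AARS1, NARS1 and EPRS1. Of these 15 had a positive log2 fold change, with a median of 0.26 (camera p = 0.000109; p = 0.0851 with an estimated correlation), and 0 passed singly. The 15 mitochondrial synthetase genes had a median of 0.04. Without FBSA replicate 2 the median of the 16 was 0.18, which argues against that library as the sole origin. The highest absolute median of the other splits was 0.15, with a camera p as low as 0.000776, so the group rise remains a hypothesis, and a difference between pools could also give it.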
